A study of Mus musculus with 4 samples.

How the data were processed

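RNA of 4 mouse cell populations was hybridised to Affymetrix arrays, 1 array per population. The populations were club cells of adult lung as isolated (Day0), the same cell type after 3 weeks in medium with doxycycline (3w+Dox), after 2 further weeks without it (3w+Dox+2w-Dox), and iPS cells made from club cells. Groups were taken from the sample titles and descriptions. Per the labels' protocols, total RNA was extracted with RNeasy columns, prepared with the Ambion WT kit and labelled with biotin. The labels name no sort or gate for the isolate and no feeder layer for the cultures.

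The deposited table holds log2 signals that the authors made with RMA, which corrects background, quantile normalizes probes over arrays and summarises each probe set by median polish. RMA, the affy package and R 3.0.2 are named per the submitters' processing notes, and the log2 scale was read from the values, which lie between 1.70 and 13.85 with near-equal quantiles on the 4 arrays. The annotation behind the probe sets and its version are not given in the sources used here. The table has 25206 probe sets, each named by an Entrez gene ID. The platform annotation gave 1 gene symbol for 23185 of them and several for 0, and 2021 stayed unnamed and were left out of comparisons by gene. All 23185 gene IDs were found in a RefSeq gene table, with 0 symbols that differed. Every named gene had 1 probe set, so no rule for several probe sets was needed. The genome build is not named, so no coordinates are given. The table had 0 missing values. The number of arrays, and not a read depth, limits precision. No values were normalized or transformed again for the main results.

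With 1 array per population, the spread between replicates cannot be estimated and no p-value was computed. Each of 6 pairwise comparisons is a difference of log2 signals, and a gene counts as higher or lower when the difference is at least 2 log2 units (4-fold) and the brighter array lies at or above the median of all values (6.67). For genes that differed in this way between 3w+Dox and Day0, the share within 1 log2 unit (2-fold) of Day0 after withdrawal was taken with a 95% Wilson interval over genes, and the share of each log2 difference undone was computed. For genes that differed between iPS and Day0, the position of each culture was the difference from Day0 as a percent of the iPS difference. Intervals over genes describe the spread among genes on these arrays, not the spread between cultures.

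The 31 gene lists, the thresholds, the rule for named genes and the alternatives were chosen before the data were examined. The lists cover club, ciliated, basal, alveolar type 1, alveolar type 2, goblet and neuroendocrine cells, leukocytes, endothelial cells, fibroblasts, epithelial identity, reprogramming factors, the pluripotency network, germ layers, lung transcription factors and progenitors, proliferation, cell cycle inhibitors, xenobiotic metabolism, interferon response, MHC class I, immediate early genes, chemokines and cytokines, squamous differentiation, glycolysis, oxidative phosphorylation, cholesterol synthesis, ribosome biogenesis, chromatin, germline, imprinted genes and matrix remodelling. They name 752 genes, of which 709 were measured, 3 of them through an older symbol, and 43 had no named probe set. Each list's median difference was placed among the medians of 10000 random lists of the same size matched on the mean of both arrays in 10 bins, as a description of these arrays, and has a 95% bootstrap interval over members (2000 draws). A median outside the central 95% of the random lists counts as standing apart. Further lists of macrophage, lymphocyte, posterior Hox and lung mesenchyme genes were written after the arrays had been compared and before these lists were measured.

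The genes named are, in each comparison, the 10 largest increases and 10 largest decreases among genes counted as higher or lower, without predicted or clone-named genes, olfactory and vomeronasal receptors, immunoglobulin and T cell receptor segments and small RNAs. To these were added up to 4 members of each described list with the largest difference, and a fixed set of marker genes, the reprogramming factors among them, given on every array. The exon probe sets cannot separate Pou5f1, Sox2, Klf4 and Myc transgenes from the genes of the cell.

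Alternatives were a 2-fold and an 8-fold threshold, no filter on dim probe sets and a filter at the 75th percentile of all values (8.82), a second quantile normalization, centring of each array on the median of its brighter named genes, values below the 25th percentile (5.07) raised to it, the mean over list members, list members dim on every array left out, members of several lists left out, 20 expression bins, and a return defined by undoing at least 50% of the log2 difference. The calls were tested on simulated data from 2 copies of the Day0 array with 23185 genes and noise of 0.3 log2 units. All changes of 3 log2 units were recovered (100%), 1% of changes of 1 log2 unit and 0 unchanged genes were called, 2% of unshifted lists fell outside the central 95%, and 100% of lists shifted by 0.5 lay above it. The noise level was assumed, because no replicates exist, and the simulated lists held genes drawn at random. The simulation checks the calculation and gives no error rate for the real arrays or lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.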

Results

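Gene expression was measured on 4 Affymetrix arrays, 1 for each of 4 mouse cell populations. Club cells are secretory cells of the airway lining, and the Day0 population is given in the labels as club cells of adult mouse lung, not cultured. Markers of other lung cells were also bright at Day0, with 17 of 18 alveolar type 2 and 29 of 30 ciliated cell genes at or above 6.67, the median of all values. Sftpc and Sftpa1, surfactant proteins of alveolar type 2 cells, read 13.49 and 13.36, Ager, a receptor of alveolar type 1 cells, 11.59, and Foxj1, a factor of ciliated cells, 11.19, beside 13.52 for the club cell gene Scgb1a1. The 3w+Dox population, called Club-iPL in the labels, had spent 3 weeks in medium with doxycycline, the drug that switches on inducible transgenes. The 3w+Dox+2w-Dox population, called withdrawn cells here, had then spent 2 further weeks without the drug. The fourth population consisted of induced pluripotent stem (iPS) cells made from club cells. Signals are log2 values from RMA, with array medians of 6.60 at Day0, 6.67 at 3w+Dox, 6.74 in withdrawn cells and 6.65 in iPS cells. With 1 array per population, no difference below has a replicate check, no p-value is given, and the number of arrays limits the precision. A gene is counted as higher or lower when its signals differ at least 4-fold and the brighter one lies at or above 6.67. Where the dimmer signal is near background, the size of a fold and its rank among the largest are those computed from these arrays and are not exact. A list is described by the median difference of its measured members, with a 95% bootstrap interval over members, and by the place of that median among 10000 random lists of the same size and similar signal.

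The comparison of 3w+Dox with Day0 asks what the club cell population had become after 3 weeks with doxycycline. Genes of fibroblasts and of the extracellular matrix were far higher in the 3w+Dox cells, while genes of ciliated and club cells were far lower. All 26 measured fibroblast and mesenchymal genes were at least 4-fold higher, with a median difference of 4.87 (4.10 to 5.45). They included Postn, a matrix protein, by 7.64, Lum, a collagen-binding proteoglycan, by 6.38, Prrx1, a mesenchymal transcription factor, by 6.34, and Col1a1 (Entrez gene 12842), a chain of type I collagen, by 6.11. Of 30 ciliated cell genes, 27 were at least 4-fold lower, with a median difference of -3.10 (-3.42 to -2.84). They included Sntn, a protein of the ciliary tip (-5.68), Rsph4a, part of the radial spoke (-4.99), Dynlrb2, a dynein light chain (-4.47), and Ak7, an adenylate kinase of cilia (-4.32). Of 28 club cell genes, 15 were at least 4-fold lower and 1 at least 4-fold higher, with a median difference of -2.75 (-3.34 to -1.19).

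The club cell genes did not move by equal amounts. Scgb1a1 (Entrez gene 22287), which encodes the main secretory protein of club cells, read 13.52 at Day0, 12.62 at 3w+Dox, 13.04 in withdrawn cells and 4.18 in iPS cells, so its difference at 3w+Dox was -0.89. Cyp2f2, a club cell cytochrome P450, read 13.83, 12.44, 13.45 and 7.86 on the same arrays. Scgb3a2, a second secretoglobin, read 10.21, 6.25, 8.81 and 3.86, a 15.6-fold lower signal at 3w+Dox than at Day0. The Day0 signal of Cyp2f2 is the brightest of that array (13.83) and those of Scgb1a1 and Sftpc are close to it, so saturation can make their differences too small. The members furthest apart were Sult1d1, a sulfotransferase (-7.63), Bpifa1 and Bpifb1, secreted defence proteins of the airway (-6.61 each), and Cldn10, a tight junction protein (-5.15). Of 33 genes of xenobiotic metabolism, 15 were at least 4-fold lower and 0 at least 4-fold higher, with a median of -1.39 (-2.82 to -0.66), and Ces1f, a carboxylesterase, Fmo2, a flavin monooxygenase, and Cyp2b10, a cytochrome P450, differed by -6.12, -5.66 and -5.44. Foxj1 (Entrez gene 15223), the transcription factor that drives the building of motile cilia, read 11.19 at Day0, 7.99 at 3w+Dox, 10.45 in withdrawn cells and 8.38 in iPS cells.

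Over all named genes, 1000 were higher and 667 lower at 3w+Dox than at Day0. The 10 largest increases were those of Aspn, a matrix proteoglycan, by 8.12 (278-fold), Postn, Egln3, a prolyl hydroxylase that marks hypoxia-inducible factor, by 7.61, Col12a1, a collagen, by 7.49, Lox, which cross-links collagen, by 7.48, Thbs2, a thrombospondin, by 7.46, Tnc, the matrix protein tenascin C, by 7.17, Mmp2, a matrix metalloproteinase, by 7.17, Cd109, a membrane protein that binds TGF-beta, by 7.15, and Timp1, an inhibitor of metalloproteinases, by 7.04. The 10 largest decreases were those of Sult1d1 (198-fold), Cyp4f15, a cytochrome P450 (156-fold), Bpifa1, Bpifb1, Slc10a5, a solute carrier of the bile acid transporter family (82.4-fold), Ces1f, Agr3, a protein disulfide isomerase of ciliated cells (69.2-fold), Scgb1c1, a secretoglobin (56.1-fold), Slc23a1, a vitamin C transporter (51.4-fold), and Sntn. Matrix remodelling genes differed by a median of 3.21 (2.58 to 4.23), with 20 of 26 at least 4-fold higher, and Mmp13, a collagenase, differed by 7.02.

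Other cell types moved with the same array. Leukocyte genes differed by a median of 2.27 (-0.01 to 2.87), with 13 of 24 at least 4-fold higher. These included C1qb, a chain of complement C1q, by 5.02, Adgre1, a macrophage surface receptor, by 4.06, and Fcer1g and Tyrobp, signalling adaptors of myeloid cells, by 3.85 and 3.77. Ptprc, the pan-leukocyte antigen CD45, read 4.70 at Day0, 7.44 at 3w+Dox, 7.27 in withdrawn cells and 4.51 in iPS cells. Vim, the mesenchymal intermediate filament vimentin, read 9.17, 13.54, 13.59 and 12.97, and Col1a1 read 6.73, 12.84, 12.53 and 9.76. Epithelial identity genes differed by less, with a median of -0.42 (-0.84 to -0.32) and 3 of 27 at least 4-fold lower. The furthest apart were Prss8, a membrane protease (-2.51), Grhl1 and Ovol1, epithelial transcription factors (-2.19 and -2.06), and Krt7, a simple epithelial keratin, which was higher by 1.82. Epcam, an epithelial adhesion molecule, read 11.19, 10.77, 10.18 and 10.95, and Cdh1, which encodes E-cadherin, read 12.56, 12.20, 11.48 and 11.90.

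Among the reprogramming factors, Myc was 9.02-fold and Klf4 4.34-fold higher at 3w+Dox than at Day0, and Sox2 was 4.64-fold lower. The probe sets read exons, so a transgene and the gene of the cell itself cannot be told apart. Pou5f1, which encodes Oct4, read 6.20 at Day0, 6.51 at 3w+Dox, 5.87 in withdrawn cells and 8.87 in iPS cells, Sox2 read 10.65, 8.44, 8.85 and 12.07, Klf4 read 8.60, 10.72, 9.44 and 10.67, and Myc read 7.62, 10.79, 9.75 and 9.09. The median of these 4 genes was 1.21 (-2.21 to 3.17), at percentile 98.6 of the random lists, and the mean of the 4 genes was 0.85, at percentile 90.9. The 39 genes of the wider pluripotency network differed by a median of -0.09 (-0.19 to 0.20), at percentile 58.9. Nanog (Entrez gene 71950), a core pluripotency factor, read 6.27 at Day0 and 5.83 at 3w+Dox, Lin28a, an RNA-binding protein, 6.43 and 6.55, Zfp42, also called Rex1, 4.31 and 4.37, and Dppa5a 5.08 and 4.74. The furthest apart were Tbx3, a T-box factor, higher by 2.08, Klf5 (-1.88), Zfp296 (-1.40) and Tet1, which oxidises methylated cytosine, higher by 1.21.

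Proliferation genes were higher at 3w+Dox than at Day0 by a median of 0.58 (0.44 to 0.72), above all 10000 random lists, with 10 of 39 at least 2-fold higher. Fibroblast genes (4.87) and leukocyte genes (2.27) were higher on the same array, and the arrays do not show in which cells proliferation genes or the cell cycle inhibitors below differed. Rrm2, a subunit of ribonucleotide reductase, was higher by 2.08, E2f1, a cell cycle transcription factor, by 1.61, Tpx2, a spindle protein, by 1.44, and Ccna2, which encodes cyclin A2, by 1.34. Mki67, the proliferation antigen, read 7.71 at Day0, 8.94 at 3w+Dox, 8.60 in withdrawn cells and 11.43 in iPS cells. Cell cycle inhibitor, p53 and senescence genes were also above all random lists, with a median of 0.79 (-0.08 to 1.11), and Igfbp3, an insulin-like growth factor binding protein, was higher by 5.89, Cdkn2b by 2.81, Igfbp7 by 2.73 and Cdkn1a, which encodes p21, by 2.24. Cdkn2a, whose locus encodes p16 and Arf, read 6.85, 8.11, 8.57 and 7.12.

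Lists of other lung epithelial states showed mixed members. Goblet cell and mucin genes had a median of -0.26 (-1.13 to 1.52), at percentile 13.0, and a mean of 0.06. Of these 17 genes, 4 were at least 4-fold higher and 3 at least 4-fold lower. Muc5ac (Entrez gene 17833), the gel-forming mucin of goblet cells, was 26.5-fold higher and read 8.27 at Day0, 13.00 at 3w+Dox, 8.80 in withdrawn cells and 4.94 in iPS cells, Gcnt3, which branches mucin glycans, was higher by 3.93, and Tff1, a trefoil peptide, by 3.70. Squamous and epidermal genes had a median of 0.35 (-0.14 to 1.34) with 7 of 27 at least 4-fold higher, among them Krt13, a keratin of stratified epithelia, by 4.96, Serpinb5, which encodes maspin, by 4.63, Tgm1, a transglutaminase of the cornified envelope, by 3.62, and Sprr1a, a cornified envelope precursor, by 3.35. Airway basal cell genes had a median of 0.45 (-0.09 to 1.74), above all random lists. It was led by Snai2, a transcription factor also made by mesenchymal cells, higher by 5.65, Igfbp2 by 3.87, Aqp3, a water channel, by 2.94, and Itga6, an integrin, by 2.18. Signals of the classical basal markers at 3w+Dox were within 2-fold of Day0, and Trp63 was 2.17-fold above Day0 in withdrawn cells. Krt5 read 6.20 at Day0, 5.93 at 3w+Dox, 6.56 in withdrawn cells and 6.10 in iPS cells, and Trp63 read 6.10, 6.36, 7.21 and 6.13.

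Alveolar type 2 genes were lower at 3w+Dox by a median of -0.84 (-1.79 to -0.37), at percentile 0.010, with Hc, which encodes complement C5 (-2.86), Cd36, a fatty acid transporter (-2.58), and Sftpa1, a surfactant protein (-1.94), and with Dlk1 higher by 3.49. Sftpc, the surfactant protein that marks alveolar type 2 cells, read 13.49 at Day0, 13.39 at 3w+Dox, 13.54 in withdrawn cells and 5.50 in iPS cells. Alveolar type 1 genes had a median of 0.18 (-0.74 to 0.47), at percentile 94.4, with Cav1, which encodes caveolin, higher by 4.53, Akap5 by 2.71, and Scnn1g, a sodium channel subunit, at -4.12. Lung epithelial transcription factors and progenitor genes had a median of -0.74 (-0.92 to 0.24), below all random lists. That median was -0.36, at percentile 2.59, without members shared with other lists, and the mean over members was -0.26, at percentile 11.6. Lgr5, a receptor found on stem cells of several epithelia, was higher by 5.13, Elf5, a factor of lung and mammary epithelium, was at -4.77, and Sox9, a factor of the distal lung bud tip, read 7.18 at Day0, 9.47 at 3w+Dox, 9.13 in withdrawn cells and 7.46 in iPS cells. Nkx2-1, the lineage factor of lung epithelium, read 11.17, 9.93, 10.07 and 5.94. Fibroblast genes were higher by 4.87 at 3w+Dox, and the arrays do not show in which cells Lgr5, Sox9, Cav1 and Dlk1 differed.

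Across genes, which are not independent replicates, the 3w+Dox and Day0 arrays correlated with Pearson's r = 0.897, and the standard deviation of their differences was 1.10. Medians of 19 of the 31 lists lay outside the central 95% of the random lists, 11 above and 8 below. No array of club cells cultured without doxycycline was analysed here, so time in culture and the drug are not separated in this comparison.

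**Figure D1:**
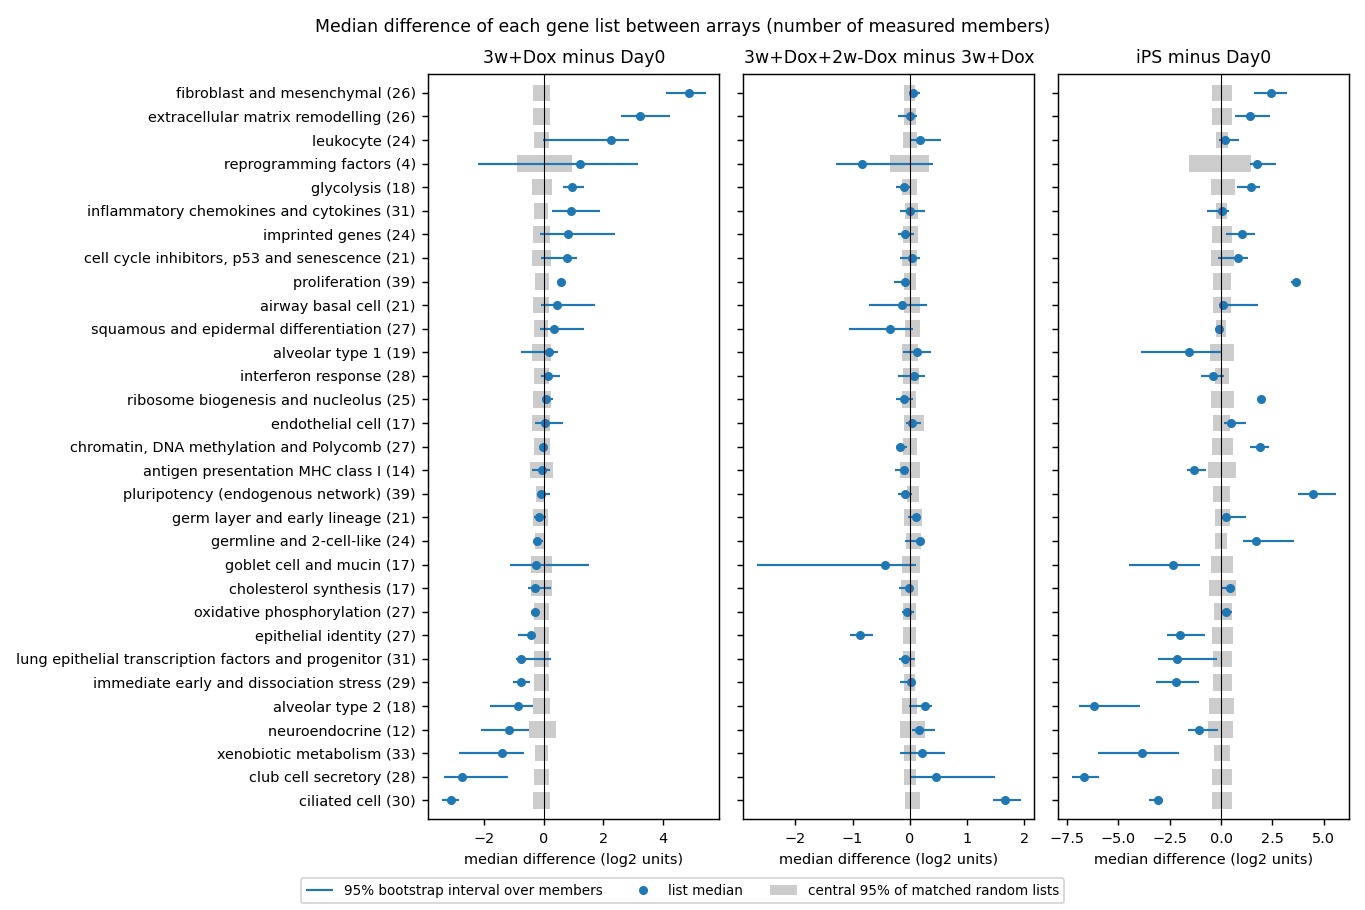
Median log2 difference of each of 31 gene lists (points, with 95% bootstrap intervals over members as lines) for 3w+Dox minus Day0, withdrawn minus 3w+Dox and iPS minus Day0, beside the central 95% of random lists matched on signal (grey bars). The fibroblast list stands at 4.87 and the ciliated list at -3.10 in the left panel, and the pluripotency list at 4.48 in the right panel.

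The comparison of withdrawn cells with 3w+Dox cells asks what changed in the 2 weeks after doxycycline was removed. Ciliated cell genes and part of the club cell genes were higher in the withdrawn cells, part of the mucous and squamous genes were lower, and fibroblast genes stayed at their 3w+Dox signals. Of 30 ciliated cell genes, 9 were at least 4-fold and 26 at least 2-fold higher, with a median of 1.66 (1.45 to 1.95), above all 10000 random lists. Sntn was higher by 3.36, Dynlrb2 by 2.94, Rsph4a by 2.77 and Foxj1 by 2.46. Club cell genes were higher by a median of 0.46 (0.02 to 1.48), with 7 of 28 at least 4-fold higher and 2 at least 4-fold lower, and the furthest apart were Bpifb1, higher by 3.38, Reg3g, an antimicrobial lectin, higher by 3.21, Lypd2 (-3.30) and Muc5b, the main mucin of club cells (-2.68).

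The largest decreases after withdrawal were those of Slurp1, a secreted epithelial protein (106-fold), Clca1, a secreted goblet cell protein (92.4-fold), Klk1, a kallikrein protease (72.8-fold), Saa1, an acute-phase protein (57.8-fold), Nccrp1 (48.8-fold), Ly6g6c (46.1-fold), Anxa10, an annexin (43.3-fold), Krt13 (41.6-fold), Gsdmc2, a gasdermin (34.1-fold), and Fam3b (30.4-fold). The largest increases were those of Meig1, by 3.65, Spata18, by 3.64, Smr2, by 3.64, Gp2, by 3.61, Bpifb1, Sntn, Agr3, by 3.26, Reg3g, Ccna1, which encodes cyclin A1, by 3.17, and Cfap206, a cilium protein, by 3.04. Goblet cell and mucin genes had a median of -0.43 (-2.68 to 0.11), below all random lists. Of these, 7 of 17 were at least 2-fold lower and 3 at least 2-fold higher, with Clca1 at -6.53, Muc5ac at -4.20, Tff1 at -3.92 and Gcnt3 at -3.52. Squamous and epidermal genes had a median of -0.34 (-1.06 to 0.06), also below all random lists. Of these, 9 of 27 were at least 2-fold lower and 2 at least 2-fold higher, with Krt13 at -5.38, Tgm1 at -3.76, Krt6b at -3.02 and Serpinb5 at -1.95. Epithelial identity genes were lower by a median of -0.87 (-1.04 to -0.64), with 11 of 27 at least 2-fold lower, and the keratins Krt7, Krt8 and Krt19 stood at -2.36, -1.73 and -1.70.

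Fibroblast and mesenchymal genes differed by a median of 0.06 (-0.01 to 0.19), with 0 of 26 at least 2-fold apart, and leukocyte genes by 0.18 (0.01 to 0.54), with H2-Ab1, H2-Eb1 and H2-Aa, chains of MHC class II, higher by 1.34, 1.15 and 1.06. Klf4, Myc and Pou5f1 were at -1.28, -1.04 and -0.63 and Sox2 was higher by 0.41. Pluripotency network genes had a median of -0.09 (-0.20 to 0.04), at percentile 0.400, with Tfcp2l1 at -1.93 and every other measured member within 1 log2 unit. The median without members shared with other lists was -0.04, at percentile 4.05. Proliferation genes had a median of -0.08 (-0.28 to -0.05), at percentile 6.06, or 1.68 after a second quantile normalization. The airway basal list had a median of -0.13 (-0.72 to 0.29) and turned to 0.20 without members shared with other lists, with Aqp3 at -3.59 and Dapl1 higher by 2.43. Only 70 genes were higher and 109 lower, r across genes was 0.981, and the standard deviation of the differences was 0.476, the smallest of the 6 comparisons.

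The return toward Day0 was measured over the genes that had differed at 3w+Dox. Of the 1000 genes higher at 3w+Dox, 76 lay within 2-fold of Day0 after withdrawal, which is 7.60% (95% Wilson interval over genes 6.11 to 9.41%), and 802 were still at least 4-fold above Day0. Of the 667 lower genes, 31 lay within 2-fold of Day0, which is 4.65% (3.29 to 6.52%), and 338 were still at least 4-fold below it. The median share of the log2 difference undone was 0.583% for the higher genes and 25.5% for the lower ones. All 28 ciliated cell genes that had been at least 2-fold lower at 3w+Dox lay closer to Day0 after withdrawal, with a median of 53.4% undone (range 32.9 to 81.5%). For 20 such club cell genes the median was 45.5% (-22.8 to 95.8%) and for 20 xenobiotic genes 24.4%. Among genes that had been at least 2-fold higher at 3w+Dox, the median undone was 112% for 6 goblet genes, 67.6% for 10 squamous genes, 70.4% for 4 interferon genes, -1.36% for 26 fibroblast genes and -3.06% for 14 leukocyte genes. The genes were picked on 2 of the 3 arrays used, so regression to the mean is part of any return.

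**Figure D2:**
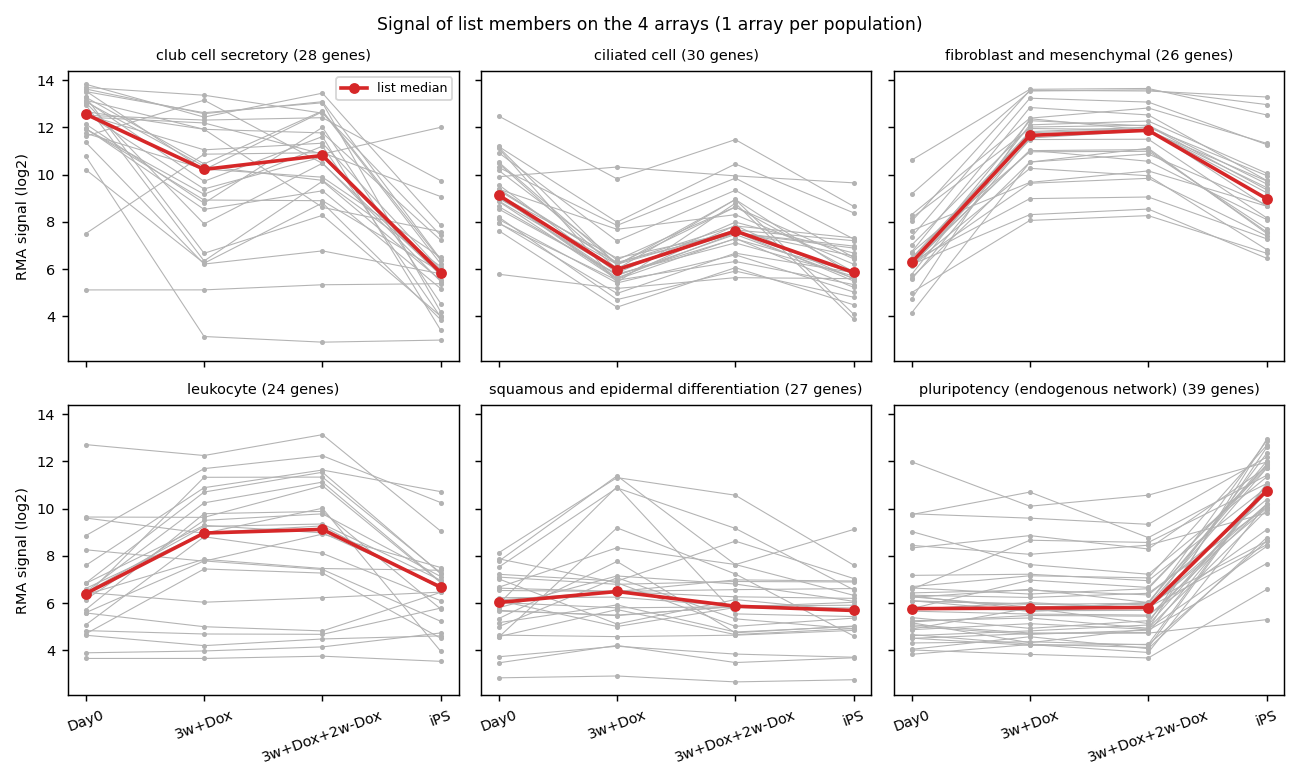
RMA signal (log2) of the measured members of 6 gene lists on the 4 arrays, with grey lines for single genes and the red line for the list median. The ciliated list drops between Day0 and 3w+Dox and is higher again in withdrawn cells, the fibroblast list stays high in both cultures, and the pluripotency list is high on the iPS array, where its median difference from Day0 is 4.48.

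The comparison of withdrawn cells with Day0 asks how far the population lay from its origin after 3 weeks with and 2 weeks without doxycycline. Matrix and fibroblast genes were still far above Day0. Ciliated genes and part of the club cell genes were still below it, and so were epithelial identity genes, by a similar median (-1.30). Fibroblast genes differed by a median of 4.94 (4.08 to 5.52), with all 26 at least 4-fold higher, and Lum by 6.97, Prrx1 by 6.50 and Thy1, a fibroblast surface antigen, by 6.30. Scgb1a1 stood at -0.48, Cyp2f2 at -0.38 and Scgb3a2, whose Day0 signal is further from the top of the scale, at -1.41 (2.65-fold lower) relative to Day0, and the club cell list at -1.39 (-2.21 to -0.80), with 9 of 28 at least 4-fold lower. Ciliated cell genes stood at -1.53 (-1.58 to -1.35), with 3 of 30 at least 4-fold lower, and Foxj1 at -0.74.

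The 10 largest increases were those of Aspn, by 7.76, Mmp13, by 7.71, Mmp2, by 7.66, Lox, by 7.42, S1pr3, a receptor for sphingosine 1-phosphate, by 7.25, Egln3, by 7.22, Col12a1, by 7.20, Postn, by 7.15, Timp1, by 7.14, and Thbs2, by 7.13. The 10 largest decreases were those of Sult1d1 (233-fold), Cyp4f15 (68.8-fold), Slc10a5 (54.9-fold), Kdr, a receptor for vascular endothelial growth factor (43.7-fold), Cnksr2 (34.2-fold), C6, a complement component (33.5-fold), Itprid1 (33.0-fold), Il1f9, a cytokine of the interleukin 1 family (32.8-fold), Bpifa1 (32.0-fold) and Slc23a1 (29.9-fold). Leukocyte genes stood at 1.98 (0.42 to 3.02) and matrix remodelling genes at 2.91 (1.60 to 4.24) above Day0, both above all random lists. Epithelial identity genes stood at -1.30 (-1.72 to -1.08), with 21 of 27 at least 2-fold lower, and Grhl1, Prss8, Ovol1 and Cldn7, a claudin, at -2.99, -2.97, -2.53 and -2.13. Myc was still 4.39-fold above Day0 and Lgr5 was higher by 4.89. Xenobiotic genes stood at -1.52 (-1.86 to -0.87) and goblet genes at -0.81 (-1.27 to -0.25), and the squamous list was at 0.01 (-0.18 to 0.19), or 0.39 without members dim on every array. In all, 939 genes were higher and 430 lower, with r = 0.908 across genes and a standard deviation of 1.03.

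The comparison of iPS cells with Day0 asks how pluripotent cells differ from the club cells. The pluripotency network and the cell division genes were far higher in iPS cells, and the genes of every lung epithelial type measured except the basal list were lower. Of 39 pluripotency genes, 35 were at least 4-fold higher, with a median of 4.48 (3.72 to 5.60), led by Utf1, a chromatin factor of pluripotent cells, by 8.06 (266-fold), Tdgf1, a Nodal co-receptor, by 7.68, Nanog, by 6.60, and Nr0b1, a nuclear receptor, by 6.55. Nanog read 12.87 in iPS cells, Lin28a 10.38, Zfp42 8.62 and Dppa5a 5.30, and in withdrawn cells these genes read 5.96, 6.35, 4.24 and 4.73. Of 39 proliferation genes, 37 were at least 4-fold higher, with a median of 3.66 (3.42 to 3.91), and the mitotic checkpoint kinases Bub1 and Bub1b were higher by 5.17 and 4.70, the motor protein Kif11 by 4.59 and the mitotic kinase Aurka by 4.39.

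Club cell genes were lower in iPS cells than at Day0 by a median of -6.67 (-7.27 to -5.95), alveolar type 2 genes by -6.20 (-6.91 to -3.93), xenobiotic genes by -3.85 (-5.97 to -2.05), ciliated genes by -3.08 (-3.50 to -2.81), goblet genes by -2.32 (-4.49 to -1.01), lung transcription factors and progenitor genes by -2.15 (-3.07 to -0.22) and alveolar type 1 genes by -1.57 (-3.91 to 0.04), all below every random list. The basal list stood at 0.09 (-0.11 to 1.78), inside the central 95% of random lists, and its mean of 0.68 lay above it, with Krt17, a keratin, higher by 4.79. The iPS signals of Ces1d, Scgb1a1, Bpifa1, Pon1, Cxcl15, Cyp2b10, Retnla and Sult1d1 lie below 5.07, the 25th percentile of all values. Their folds and order therefore have no reliable size. The 10 largest decreases as computed were those of Ces1d, a carboxylesterase (843-fold), Scgb1a1 (645-fold), Bpifa1 (620-fold), Pon1, a paraoxonase (617-fold), Cxcl15, a lung chemokine (360-fold), Cyp2b10 (297-fold), Sec14l3, a lipid-binding protein (266-fold), Sftpc (255-fold), Retnla, a resistin-like protein (250-fold), and Sult1d1 (220-fold). Besides Utf1, Tdgf1, Nanog and Nr0b1, the 10 largest increases were those of Zfp981, a zinc finger protein, by 7.08, Slc2a3, a glucose transporter, by 6.83, Trh, the precursor of thyrotropin-releasing hormone, by 6.50, Zfp979, by 6.40, Fbxo15, an F-box protein of pluripotent cells, by 6.36, and Dppa4, by 6.35.

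Other groups also differed between iPS cells and Day0. Ribosome biogenesis genes were higher in iPS cells than at Day0 by a median of 1.95 (1.85 to 2.05), with 22 of 25 at least 2-fold higher, among them Heatr1 and Utp20, factors of ribosomal RNA processing, by 2.62 and 2.52, Srm, spermidine synthase, by 2.54, and Gnl3, nucleostemin, by 2.51. Chromatin, DNA methylation and Polycomb genes were higher by 1.88 (1.42 to 2.31), with Tet1 at 5.96, Dnmt3l, a cofactor of DNA methyltransferases, at 5.70, Hells, a chromatin remodeller, at 4.66 and the DNA methyltransferase Dnmt3b at 4.10. Germline and 2-cell-like genes were higher by 1.72 (1.07 to 3.55), with Dazl at 4.81, Mael at 4.59, Tdrd12 at 4.59 and Ddx4 at 4.36, all germ cell genes. Glycolysis genes were higher by 1.46 (0.78 to 1.92), with Slc2a3, Pfkp, a phosphofructokinase, at 2.82, Pgam1, a mutase, at 2.15, and Slc16a3, a lactate transporter, at 2.09. Fibroblast genes were higher by 2.41 (1.61 to 3.23), with 15 of 26 at least 4-fold higher and Fn1, which encodes fibronectin, at 5.26, and matrix remodelling genes by 1.42 (0.68 to 2.38). Epithelial identity genes stood at -2.0 (-2.64 to -0.78), with Ehf, an epithelial ETS factor, at -5.03, Krt19 at -3.78, Cldn3 at -3.69 and Cldn6 higher by 3.38. The 4 reprogramming factors had a median of 1.77 (1.42 to 2.67). In all, 1134 genes were higher and 1368 lower, with r = 0.845 across genes, the lowest of the 6 comparisons, and a standard deviation of 1.34.

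The comparisons of iPS cells with the 2 doxycycline-derived cultures ask how far these cultures were from pluripotency. Pluripotency genes were higher in iPS cells than in 3w+Dox cells by a median of 4.21 (3.71 to 5.45), with 35 of 39 at least 4-fold higher, and than in withdrawn cells by 4.39 (3.64 to 5.43), with 36 of 39. Nanog was 131-fold higher in iPS cells than in 3w+Dox cells and 120-fold higher than in withdrawn cells, Utf1 223-fold and 263-fold, Zfp981 207-fold and 184-fold, Tdgf1 111-fold and 175-fold, Nr0b1 116-fold and 112-fold, Fbxo15 109-fold and 120-fold, Trh 101-fold and 99.7-fold, Zfp979 89.0-fold and 109-fold, and Apela, a peptide hormone of pluripotent cells, 88.2-fold and 92.9-fold. The lists of 10 ended with Dnmt3l, 77.2-fold higher than at 3w+Dox, and Platr10, a noncoding RNA, 85.4-fold higher than in withdrawn cells. Proliferation genes were higher in iPS cells by 3.06 (2.81 to 3.36) and 3.30 (2.99 to 3.50).

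Club and alveolar genes were lower in iPS cells than in either culture, while basal genes (-0.22 and 0.17) and neuroendocrine genes (0.14 and 0.02) differed little from 3w+Dox and withdrawn cells. Club cell genes differed by -3.86 (-4.46 to -2.62) from 3w+Dox cells and by -4.63 (-5.26 to -3.60) from withdrawn cells, and Scgb1a1 was 347-fold and 464-fold lower. Against 3w+Dox cells, the largest decreases beside Scgb1a1 were those of Muc5ac (267-fold), Sftpc (237-fold), Ltf, which encodes lactoferrin (230-fold), Cxcl15 (228-fold), Muc5b (169-fold), Anxa10 (143-fold), Slurp1 (134-fold), Sprr2a3, a cornified envelope precursor (124-fold), and Ctse, a cathepsin (116-fold). Against withdrawn cells they were those of Cxcl15 (311-fold), Ces1d (295-fold), Sftpc (263-fold), Reg3g (176-fold), Retnla (151-fold), Ltf (125-fold), Sftpb, a surfactant protein (118-fold), Slc34a2, the phosphate transporter of alveolar type 2 cells (113-fold), and Cbr2, a carbonyl reductase (103-fold). Fibroblast genes were lower in iPS cells by -2.14 (-2.92 to -1.81) and -2.32 (-2.68 to -1.92) and leukocyte genes by -2.38 (-2.77 to -0.29) and -2.21 (-2.76 to -0.91). Ciliated genes were close to the 3w+Dox signals, with a median of -0.11 (-0.42 to 0.11), and were lower than in withdrawn cells by -1.66 (-2.08 to -1.26). In all, 827 genes were higher and 1196 lower than at 3w+Dox, and 888 higher and 1170 lower than in withdrawn cells, with r = 0.882 and 0.880 across genes.

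The place of the 2 cultures between Day0 and iPS cells was measured over the 2502 genes at least 4-fold apart between those arrays. The median gene lay 37.5% (95% bootstrap interval over genes 34.9 to 40.1%) of the way to its iPS signal at 3w+Dox and 36.0% (33.9 to 38.2%) after withdrawal. Genes lower in iPS cells lay further along than genes higher in iPS cells, with medians of 50% and 20.5% at 3w+Dox and of 45.0% and 15.8% after withdrawal. The Day0 signal enters the choice of genes and both differences, so any signal found at Day0 alone gives a positive share, and 338 genes stood at least 4-fold above and 803 below both cultures at Day0. No value for the absence of a relation to iPS cells is available here, and the percentages describe a place on this scale only. Single genes can lie far from these medians. Among the higher genes, Nanog, Utf1 and Zfp42 read 5.83, 5.13 and 4.37 at 3w+Dox, near their Day0 signals of 6.27, 4.88 and 4.31. Among the lower genes, Scgb1a1 and Sftpc read 12.62 and 13.39 at 3w+Dox, nearer to Day0 (13.52 and 13.49) than to iPS cells (4.18 and 5.50).

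**Figure D3:**
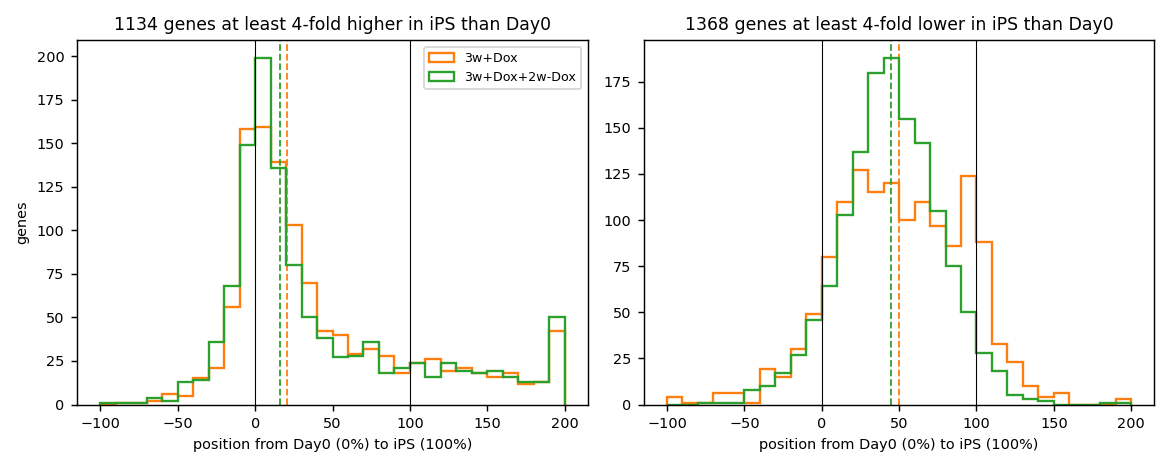
Position of each gene from its Day0 signal (0%) to its iPS signal (100%) in 3w+Dox and withdrawn cells, as counts of genes per bin, for 1134 genes higher and 1368 genes lower in iPS cells, with dashed lines at the medians and values beyond the axis placed in the end bins. The medians of the higher genes are 20.5% and 15.8% and those of the lower genes 50% and 45.0%.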

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

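The differences of named genes stayed within 0.17 log2 units of their main values under both rescalings of the arrays (889 differences). Those of at least 2 log2 units kept their direction, and the direction of smaller ones was not checked. The rescalings moved the median of all genes by at most 0.04. Counts of higher and lower genes stayed within 1.5 times under these rescalings, without a filter on dim probe sets and with dim values raised, and the probe set rule changed nothing because every gene has 1 probe set. The thresholds moved the counts by their construction. At 2-fold, higher and lower genes numbered 2010 and 1743 (3w+Dox minus Day0), 337 and 437 (withdrawn minus 3w+Dox), 1821 and 1800 (withdrawn minus Day0), 3038 and 2885 (iPS minus Day0), 2639 and 2885 (iPS minus 3w+Dox), and 2669 and 2899 (iPS minus withdrawn). At 8-fold they numbered, in the same order, 505 and 251, 10 and 41, 511 and 124, 543 and 632, 332 and 427, and 362 and 398. The share of higher genes in the withdrawn minus Day0 comparison was 68.6% at 4-fold, 50.3% at 2-fold and 80.5% at 8-fold. With the filter at the 75th percentile, 420 genes were lower at 3w+Dox than at Day0 and 28 higher after withdrawal, since fewer genes can pass. Genes back within 2-fold of Day0 made up 17.9% of the higher and 19.97% of the lower genes when 2-fold differences were followed, and 5.94% and 2.79% when 8-fold differences were. With a return defined as at least 50% undone, the shares were 10.2% and 18.9%, higher for the lower genes, as at 2-fold, while the main definition and 8-fold gave the opposite order, and these differences were not tested. The positions between Day0 and iPS were 30.3% (3w+Dox) and 30.5% (withdrawn) over 2-fold genes, which puts withdrawn cells slightly ahead, and 33.0% and 33.2% with the 75th percentile filter, where the cause was not tested. Of 186 list medians, 115 stood apart from random lists. That changed for 6 under a second quantile normalization, 8 without dim members, 12 without shared members, 17 with the mean and 0 with centring or 20 bins. The basal list's median after withdrawal turned from -0.13 to 0.20 without shared members, at percentile 96.7. Dim signals limit the lowest values, because differences between probe sets near background have no reliable size.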

Other observations

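The tests of a change of the whole epithelium, of dilution, of single-array noise and of the epithelial share (against both arrays) were chosen only after the result was seen, and those of macrophage, Hox and lung mesenchyme genes before it was measured. Several gene groups outside the comparisons above also differed. Imprinted genes were higher at 3w+Dox than at Day0 by a median of 0.83 (-0.14 to 2.39). Of 24, 9 were at least 4-fold higher and 1 at least 4-fold lower, and at 2-fold these were 10 and 4. The imprinted median stayed at 0.58 above Day0 in withdrawn cells and at 1.02 in iPS cells. Fibroblast genes were higher on the same arrays, by 4.87, 4.94 and 2.41. Mest was higher by 4.90, the noncoding RNA H19 by 4.73, Peg3 by 3.65 and Dlk1 by 3.49 at 3w+Dox, and 10 such genes that had been at least 2-fold higher had a median of 5.68% undone, beside -1.36% for 26 fibroblast genes. Chemokine and cytokine genes were higher at 3w+Dox by 0.92 (0.30 to 1.89), among them Saa1 by 5.53, Ccl7 by 5.30, Csf1, the growth factor of macrophages, by 5.09 and Ccl2 by 4.59. Leukocyte genes (2.27) and the fibroblast genes were higher on the same array, and which cells made the chemokines was not tested. Interferon response genes had a median of 0.13 at 3w+Dox and of -0.37 in iPS cells, and MHC class I genes of -0.06 and -1.31, with H2-D1 at -2.68 and H2-K1 at -2.41 in iPS cells. Immediate early and dissociation stress genes were highest at Day0, with medians of -0.75 at 3w+Dox and -2.20 in iPS cells, and Hspa1a, a heat shock protein, stood at -2.88 and -5.33.

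Neuroendocrine genes were lower at 3w+Dox by a median of -1.17 (-2.11 to -0.48), with Resp18 at -3.48 and Snap25 at -2.42. Endothelial genes had a median of 0.06, with Kdr at -5.68 and Eng higher by 4.41. Germ layer genes had a median of -0.17 (mean 0.10), with Elf5 at -4.77, Krt20 higher by 3.26 and Meox1, a mesodermal factor, by 2.99. Glycolysis genes were higher at 3w+Dox by 0.96 (0.64 to 1.37), led by Slc2a3 by 3.82, beside 4.87 for fibroblast and 2.27 for leukocyte genes on the same array, while oxidative phosphorylation genes stood at -0.30, cholesterol synthesis genes at -0.28, ribosome biogenesis genes at 0.07, chromatin genes at -0.01 (mean 0.06) and germline genes at -0.21. The chromatin protein genes Hmga2 and Cbx7 moved apart, at 2.56 and -2.51. Dppa5a differed by 0.22 between iPS cells and Day0, against 6.60 for Nanog.

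Fibroblast, matrix and leukocyte genes were high in both doxycycline-derived cultures. Of the 26 fibroblast and 24 leukocyte genes, 10 and 8 lay at or above 6.67 at Day0, and 0 are in another list. A change of the epithelium as a whole to a mesenchymal state was taken to lower epithelial identity genes by at least 2 log2 units. Their median was -0.42 (-0.84 to -0.32) at 3w+Dox and -1.30 (-1.72 to -1.08) in withdrawn cells, with 21 of 27 at least 2-fold lower there. Both intervals lie above that limit. It was set after the values were seen, so the comparison does not decide against such a change. A mesenchymal change in all or part of the epithelial cells stays open. Macrophages may be in the cultures, since a second list of 27 macrophage genes, 3 of them at or above 6.67 at Day0, was higher by 2.87 (1.5 to 3.15), while 17 T and B lymphocyte genes had a median of -0.10. In this second list, 22 of 27 genes were at least 2-fold higher and 1, Cd14, at least 2-fold lower. Gpnmb, Trem2 and Mrc1 read 10.54, 10.42 and 10.15 on the 3w+Dox array, and Gpnmb also read 9.19 on the iPS array. Cd14 and Lcp1 read 9.03 and 11.15 at 3w+Dox, below their Day0 signals of 10.67 and 12.07. After withdrawal the second list was higher than at 3w+Dox by 0.56 (0.17 to 0.84), with 20 of 27 members above 0, while epithelial identity genes were lower by a median of -0.87.

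For the fibroblast genes, a candidate source is embryonic fibroblasts from outside the lung, because 19 posterior and Hoxc genes, 0 of them at or above 6.67 at Day0, were higher at 3w+Dox by 1.77 (0.87 to 2.19), with Hoxd13, Hoxc6 and Hoxc8 at 9.22, 9.03 and 8.33. All 19 were above Day0, but only 12 reached 6.67 on either array and only 12 were at least 2-fold higher. Hoxc4 and Hoxc13 differed by 0.32 and 0.38. The list does not tell from which part of the body such cells would come. Mesenchymal cells of the lung stay possible too, since 11 lung mesenchyme factors, 1 of them at or above 6.67 at Day0, were higher by 1.11 (0.13 to 2.57), with Meox2, Tbx4 and Foxf1 at 9.09, 8.32 and 8.24. Of these 11, 9 were above Day0, but only 5 reached 6.67 on either array, and Tcf21 and Hoxa5 read 5.58 and 6.09 at 3w+Dox. Tbx4 and Tbx5 are also made in limb mesenchyme, so the lists do not separate these sources fully. On the iPS array fibroblast genes stood 2.41 and matrix genes 1.42 above Day0, with all 26 fibroblast genes above it, while macrophage genes differed by 0.05, posterior and Hoxc genes by 0.29 and lung mesenchyme factors by 0.07. Fibroblast genes were thus also higher where these other lists differed little. These small medians do not separate the sources. Fibroblast genes on the iPS array lay 2.14 below 3w+Dox, and only 3 of 19 posterior and Hoxc genes reached 6.67 at Day0 or in iPS cells. Among the 19, Hoxc6 read 7.10 in iPS cells, 1.62 above Day0. The posterior and Hoxc median was small there but lay at percentile 97.9 of random lists, with 16 of 19 genes above Day0. Whether iPS cells or other cells on that array made the fibroblast genes was not tested. The labels name neither feeders nor a sort. Activation of Hox and mesenchymal genes in the reprogrammed cells themselves was not tested and stays open.

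Club and ciliated cell genes were lower at 3w+Dox while genes of fibroblasts and leukocytes were higher. Dilution alone would lower them no further than epithelial identity genes. At 3w+Dox the club list lay -2.33 (-2.92 to -0.57) and the ciliated list -2.68 (-3.02 to -2.18) from the epithelial identity median. These values argue against dilution as the whole cause at 3w+Dox, although the comparison was chosen after they were seen. In withdrawn cells the club list stood at -1.39 (-2.21 to -0.80) and the ciliated list at -1.53 (-1.58 to -1.35) relative to Day0. Epithelial identity genes stood nearby at -1.30 (-1.72 to -1.08), so dilution as the whole cause stays open for withdrawn cells. Part of the 3w+Dox difference may also come from dilution, and how much is not known. Scgb1a1 differed by under 1 log2 unit, but saturation can make that difference too small. Loss of ciliated cells that were in the Day0 isolate, loss of ciliated and secretory genes within cells, and time in culture without regard to doxycycline stay open, since no value here separates them.

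Part of the mucous and squamous genes were high on the 3w+Dox array alone. Of the 44 goblet and squamous list members, 7 (15.9%) stood at least 4-fold above both Day0 and withdrawn cells, against 73 of all 23185 genes (0.315%), a ratio of 50.5 (25.2 to 93.3). The lists were picked because members were seen high on this array, so the ratio does not decide against noise of a single array, which stays open. The 7 were Muc5ac, Clca1, Gcnt3, Tff1, Krt13, Krt6b and Tgm1. A larger share of epithelial cells as the whole cause was taken to raise epithelial identity genes by at least 2 log2 units. This is the cutoff that picked the 7 genes, and it was set after the values were seen. The median excess of epithelial identity genes at 3w+Dox was -0.42 (-0.84 to -0.32) over Day0 and 0.87 (0.64 to 1.04) over withdrawn cells. A median below Day0 argues against a larger epithelial share than at Day0. The comparison with withdrawn cells does not decide, because its limit was set afterwards, and that excess may account for part of the later decrease. Dependence on doxycycline, time in culture, the medium and the state of 1 culture dish were not tested and stay open, since no array without the drug at 3 weeks was analysed here.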
